A study of Homo sapiens with 21 samples.

How the data were processed

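The series holds 21 samples of the human cell line HK-2: 4 vehicle and 4 cyclosporine A mRNA libraries, 4 and 4 miRNA libraries, 2 and 2 AGO2 PAR-CLIP libraries, and 1 PAR-CLIP sample with an antibody to all Argonaute proteins. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, cells received 5 µg/mL cyclosporine A or 0.1% ethanol for 48 h before mRNA and miRNA sequencing, and for 24 h before PAR-CLIP, with 100 µM 4-thiouridine and crosslinking at 365 nm (0.15 J/cm2). Polyadenylated RNA and a small RNA fraction were sequenced, per the labels' protocols.

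The authors deposited raw counts per gene symbol and raw counts per mature miRNA as whole numbers. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt, Bowtie, TopHat, HTSeq and DESeq2 were used with build hg19; their roles, settings and other versions are not given in the sources used here. Whether counting used the strand is likewise not given in the sources used here, so reads of antisense or overlapping genes cannot be told apart. The authors also deposited tables of their own comparison with log2 fold changes and p-values, which were used only to count shared calls. The mRNA table has 23368 features, of which 28 carry a calendar date in place of a gene symbol; these stayed in the fit and were never named. The miRNA table has 2586 features. Total counts per library ranged from 3965431 to 7041604 for mRNA and from 6664231 to 9184278 for miRNA.

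Each PAR-CLIP list gives, per the file headers, a position, an annotation, a sequence and a peak score per cluster. The unit of the authors' score, the cluster caller and its filters are not given in the sources used here; the 2 libraries of a treatment are pooled in 1 list. Scores were therefore used only to rank, filter or weigh clusters within a list, and the planned ratios of score share between lists were not computed. In the list for all Argonaute proteins, the sequence length equalled the interval in 2692 of 19306 clusters, so its sequences were not used, and its treatment is not given in the labels. Coordinates are those of the lists in hg19, written 1-based. No genome was used, so sequences come from the lists.

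mRNA and miRNA counts were each fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, quasi-likelihood test of cyclosporine A against vehicle with group as the only term), and p-values were adjusted by the Benjamini-Hochberg method; an adjusted p under 0.05 is a call. A printed fold change is log2, cyclosporine A over vehicle, with the standard error implied by its F statistic. Levels are CPM after TMM, given as mean ± SD over 4 libraries. Lists were tested two-sided with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated; p-values were adjusted over 23 mRNA or 12 miRNA lists. The lists were ER stress, ATF4 targets, calcineurin and NFAT, cyclophilins, TGF-beta and matrix, epithelial-mesenchymal markers, cell cycle, p53 targets, NRF2, cholesterol, NF-kB, interferon-stimulated genes, kidney injury, proximal tubule, distal tubule, endothelial with stromal and podocyte, immune cell, hypoxia, MAPK feedback, autophagy, heat shock, microRNA pathway, mitochondrial mRNAs and junctions, and 12 lists of miRNAs.

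The named genes were drawn from a rule written before the data were examined: the 10 largest rises and 10 largest falls among calls with a mean of at least 50 counts and no overlap between the groups, up to 4 members of each mRNA list and 3 of each miRNA list by p-value, the 5 most abundant miRNAs, a set of fixed genes (among them *RCAN1*, *PPIA*, *PPIB*, *PPP3CA*, *PPP3R1*, *EIF2C2*, *HAVCR1*, *LCN2* and *TGFB1*) and miR-21, and the 5 genes with the highest 3' UTR score per AGO2 list. Some genes that the rule selects are not reported here, and counts over all genes or lists include them. Further list members are named as examples after their values were seen.

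Cluster lists were compared with bedtools 2.31.1, 1 base or more on the same strand, and chance was estimated from 20 random placements. Shares have 95% Wilson intervals. The strand share uses the first 2 clusters by position of each gene symbol in a list and class. Seed sites are the complement of miRNA positions 2 to 8, counted against 20 shuffles that keep dinucleotides. Ribosomal RNA was marked by annotation or a shared 20-base stretch, and 15 conserved stretches of bacterial 16S and 23S rRNA, typed from memory, were searched as 13-base windows in the remaining clusters. That set was revised after a first count: stretches shared by all domains of life were dropped and variants of 23S stretches were added, some after the sequence of the *ADRB1* cluster was seen. Sets of mRNA genes per seed family were planned for families with at least 10 genes; the largest had 8, so none was tested.

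Steps were tested on simulated data with known answers. In 12855 simulated mRNA genes edgeR recovered 44 of 50 changes of 1.5-fold, 45 of 50 of 2-fold, 49 of 50 of 4-fold and 50 of 50 of 8-fold, with 7 calls among 12655 unchanged genes. Far fewer mRNA genes changed in the simulation than were called in the data, evenly in both directions, so these rates need not hold there. In 470 simulated miRNAs it recovered 35, 45, 50 and 50 of 50, with 8 calls among 270 unchanged miRNAs. Many more miRNAs changed in this simulation than the 53 called in the data, so these rates need not hold there either. A simulated raised list had a camera p of 2.36e-67 for mRNA and 1.87e-08 for miRNA, and an unchanged list 0.839 and 0.811. Simulated genes were drawn independently, so this does not test camera on lists whose members are correlated. Alternatives were DESeq2 1.42.0, RLE and upper quartile normalization, no filter and a filter of 5 CPM in 4 libraries, limma voom, a replicate block, each library left out, and stricter cluster and shuffle settings. Python 3.11.15 with pandas 2.3.3 was used for the cluster lists.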

Results

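HK-2 cells, an immortalised line of human kidney proximal tubule epithelium, were exposed to cyclosporine A or to vehicle. Cyclosporine A binds cyclophilins, and the complex inhibits the phosphatase calcineurin; the drug suppresses the immune system and can injure the kidney. The series set out to define which microRNAs and mRNAs take part in the renal toxicity of calcineurin inhibitors. Polyadenylated RNA and small RNA were sequenced after 48 h at 5 µg/mL cyclosporine A or in 0.1% ethanol, with 4 libraries per treatment for each RNA class. RNA bound to the microRNA effector protein AGO2 was recovered by PAR-CLIP, in which 4-thiouridine built into RNA is crosslinked to protein by ultraviolet light, after 24 h of either treatment. The labels list 2 AGO2 libraries per treatment, and each treatment has 1 list of binding clusters. For 1 further PAR-CLIP sample, made with an antibody to all Argonaute proteins, the labels give no treatment.

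Total counts in the mRNA table were 7041604, 5366260, 4644613 and 4289120 in vehicle replicates 1 to 4, and 5001669, 4183569, 4426350 and 3965431 in cyclosporine A replicates 1 to 4. The miRNA table held 6664231 to 7888220 counts per vehicle library and 7045150 to 9184278 per cyclosporine A library. hsa-miR-21-5p alone took 54.7% to 62.6% of the miRNA counts of a library, so the other miRNAs were measured with the remainder. No pair of libraries within a group agreed within sampling noise, with a chi-square per degree of freedom of 1.27 or more for mRNA and 26.1 or more for miRNA. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

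The first comparison asked which mRNAs differ after 48 h of cyclosporine A. Several genes of lipid use were among the 10 largest rises, a grouping read from the result and not tested. *ANGPTL4*, which encodes an inhibitor of lipoprotein lipase, rose from 63.9 ± 5.01 to 1596 ± 54.5 CPM (counts scaled to library size; mean ± SD, n = 4 libraries per group), a log2 fold change of 4.65 ± 0.07 (SE). *PLIN2*, a lipid droplet coat protein, rose by 3.72 ± 0.07 on the log2 scale. *CPT1A*, which carries fatty acids toward mitochondrial oxidation, rose by 4.13 ± 0.18, and *PDK4*, a kinase that restrains pyruvate oxidation, by 3.58 ± 0.14. *PLIN5*, another lipid droplet protein, went the other way, from 27.0 ± 3.02 to 1.43 ± 0.838 CPM. Further rises among the 10 largest were *ATP6V0D2* (a vacuolar ATPase subunit, 4.41 ± 0.15), *HES1* (a Notch-responsive repressor, 3.71 ± 0.13), *GADD45A* (a stress-induced growth arrest gene, 3.43 ± 0.10), *NR1D1* (a circadian repressor, 3.10 ± 0.12), *UPP1* (uridine phosphorylase, 3.10 ± 0.07) and *ZNF697* (2.99 ± 0.09).

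The 10 largest falls included secreted and cell surface proteins, a lipid droplet protein and a transcription factor. *DEFB1*, which encodes an antimicrobial peptide of epithelia, fell from 41.8 ± 1.52 to 0.353 ± 0.239 CPM, a log2 fold change of -6.80 ± 0.23 with no count in 1 cyclosporine A library. *MMP7*, a secreted matrix protease, changed by -5.96 ± 0.14, and *FLRT3*, a cell surface adhesion protein, by -5.10 ± 0.13. The phosphate transporter gene *SLC34A2* changed by -4.86 ± 0.14, the kidney cadherin *CDH16* by -3.91 ± 0.15 and *CLDN2*, a pore-forming claudin of the proximal tubule, by -4.02 ± 0.13. *SAA2* (-4.30 ± 0.22), an acute phase protein whose reads may be shared with its near copy *SAA1*, *LRG1* (-3.92 ± 0.15) and *STAT4* (-4.23 ± 0.20) completed the 10 largest falls with *PLIN5* (-4.21 ± 0.21).

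**Figure D1:**
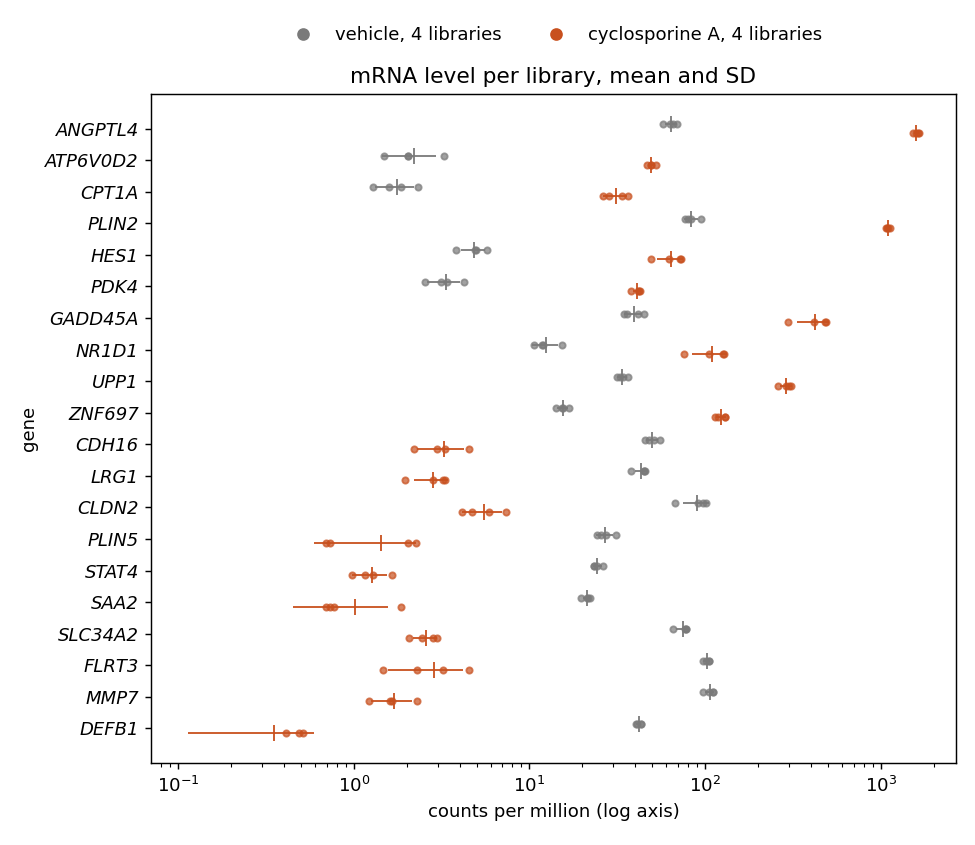
mRNA level in CPM (horizontal log axis) of the 10 genes with the largest rise and the 10 with the largest fall; points are single libraries, ticks are group means and bars are 1 SD, for 4 vehicle and 4 cyclosporine A libraries. The groups do not overlap for any of these genes; *ANGPTL4* lies at 1596 CPM with cyclosporine A against 63.9 CPM with vehicle, and 1 cyclosporine A library without a *DEFB1* count is not drawn.

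In the edgeR quasi-likelihood test, 8597 of 12855 genes passed a Benjamini-Hochberg adjusted p of 0.05, 4285 higher and 4312 lower with cyclosporine A. A change of at least 1 on the log2 scale was reached by 567 of the higher and 996 of the lower genes, and a change of at least 2 by 57 and 169. The edgeR adjusted p of the 20 genes named above ranged from 8.55e-51 for *ANGPTL4* to 1.96e-24 for *SAA2*. In the authors' deposited table, 7993 genes had an adjusted p under 0.05. Of these, 7616 were also called in the fit made here, and all 7616 had the same sign in both.

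Stress response lists rose. Each list named in what follows was fixed before the data were examined, and its counts were the same when p-values were adjusted over the list alone, except where stated. Of 29 tested targets of ATF4, the transcription factor of the amino acid response, 28 rose. They included *ASNS* (asparagine synthetase, 1.44 ± 0.06), *SLC3A2* (an amino acid transporter subunit, 1.60 ± 0.07) and the tRNA synthetase genes *AARS* (1.44 ± 0.06) and *SARS* (1.37 ± 0.06); *PSPH* did not pass (0.03 ± 0.13). Camera, a test of a list against all other genes, gave an adjusted p of 3.24e-10 for the ATF4 list, and adjusted p = 0.0980 with an estimated correlation. Of 22 endoplasmic reticulum stress genes, 18 rose and 4 did not pass. *DDIT3*, a transcription factor of that stress, changed by 2.11 ± 0.07, *HSPA5*, the main chaperone of the compartment, from 1839 ± 123 to 5099 ± 309 CPM, and *DNAJB9* changed by 1.84 ± 0.08. This list had a camera adjusted p of 2.20e-05, and adjusted p = 0.291 with an estimated correlation. Of 18 genes of the NRF2 oxidative stress response, 16 rose and 2 fell. *TXNRD1* (thioredoxin reductase) rose by 1.91 ± 0.06, *HMOX1* (heme oxygenase) by 2.03 ± 0.09 and *NQO1* by 1.57 ± 0.08; *SLC48A1* (-0.53 ± 0.10) and *AKR1C3* (-0.97 ± 0.22) fell. The NRF2 list had a camera adjusted p of 3.80e-05, and adjusted p = 0.251 with an estimated correlation. Among 17 heat shock genes, 13 rose, 1 fell (*HSPB1*, -0.44 ± 0.06) and 3 did not pass. *HSPA1B* (2.24 ± 0.11) and *HSPA1A* (1.83 ± 0.12) are near copies, so their separate values are uncertain. Cyclosporine A replicate 3 was the lowest of its group for both (88.1 and 42.1 CPM, against at least 165 and 74.9 CPM) and for *DNAJB1* (89.5 CPM, against at least 149 CPM). The same library was the lowest of its group for other genes that rose, among them *GADD45A* (295 CPM, against at least 418 CPM), *NR1D1* (75.5 against 105), *HES1* (49.5 against 62.5), *GDF15*, *CDKN1A*, *MYC*, *ADM*, *SLC3A2* and *DDIT3*; without it the log2 fold changes of *GADD45A*, *NR1D1* and *HES1* were 3.58, 3.25 and 3.82. The heat shock list had a camera adjusted p of 0.00142, and adjusted p = 0.372 with an estimated correlation.

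Genes of MAPK feedback and the immediate early response also rose, 17 of 24, with 3 falling and 4 not passed; adjusted over the list alone, 18 rose. *DUSP5* (a phosphatase that acts on ERK, 1.81 ± 0.06), *PHLDA1* (1.76 ± 0.06) and *MYC* (1.25 ± 0.06) were higher, whereas the immediate early gene *EGR1* was lower (-2.59 ± 0.13), as were *IER2* (-0.69 ± 0.07) and *JUNB* (-0.40 ± 0.07). The camera adjusted p was 9.57e-05, and adjusted p = 0.251 with an estimated correlation. In the hypoxia and glycolysis list, 12 of 21 genes rose and 4 fell, with *HK2* (hexokinase, 1.42 ± 0.06), *NDRG1* (1.34 ± 0.06) and *ADM* (1.48 ± 0.06) higher and *EGLN3* (-0.98 ± 0.14) and *CA9* (-0.35 ± 0.08) lower. Its camera adjusted p was 0.0273, and adjusted p = 0.372 with an estimated correlation; without vehicle replicate 1 the adjusted p was 0.0527.

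Proliferation genes fell. Of 28 cell cycle genes, 24 fell, 3 did not pass and 1 rose. The proliferation marker *MKI67* went from 684 ± 16.5 to 314 ± 25.3 CPM, *RRM2* (ribonucleotide reductase) changed by -1.48 ± 0.09 and *TOP2A* (topoisomerase) by -0.98 ± 0.06; *CCND1* (cyclin D1) rose by 0.39 ± 0.08. The camera adjusted p was 4.30e-06, and adjusted p = 0.345 with an estimated correlation. In the p53 target list, 9 of 20 genes rose and 10 fell. *CDKN1A*, an inhibitor of the cell cycle, rose by 1.43 ± 0.07 and *GDF15* by 1.60 ± 0.06, whereas *BTG2* (-1.65 ± 0.22) and *FAS* (-1.01 ± 0.14) fell. The median of the p53 list was -0.31 and its mean 0.0019, camera gave the direction as up, and the adjusted p was 0.948.

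Matrix and TGF-beta genes fell in balance. Of 25 tested, 16 fell, 4 rose and 5 did not pass. *TGFBI*, a TGF-beta induced matrix protein, went from 1012 ± 48.1 to 259 ± 18.1 CPM, *TGFB2* changed by -1.78 ± 0.06 and the receptor *TGFBR2* by -1.39 ± 0.07. *TGFB1* itself changed by -0.22 ± 0.06. The genes that rose were *SMAD7* (an inhibitor of TGF-beta signalling, 1.83 ± 0.14), *MMP9* (1.06 ± 0.08), *BHLHE40* (0.78 ± 0.06) and *COL6A1* (0.22 ± 0.06). The camera adjusted p was 0.00682, and adjusted p = 0.372 with an estimated correlation. Epithelial-mesenchymal markers moved both ways, with 9 of 17 higher, 4 lower and a camera adjusted p of 0.364. *SNAI2*, a repressor of epithelial genes, rose from 4.90 ± 0.610 to 27.4 ± 3.74 CPM and *KRT18* by 0.71 ± 0.07, whereas *CDH1* (E-cadherin) changed by -2.46 ± 0.25. Of 16 tight and adherens junction genes, 8 fell and 4 rose, among them *CLDN11* (-1.03 ± 0.06), *JUP* (-0.79 ± 0.07) and *CGN* (0.71 ± 0.14), with a camera adjusted p of 0.201.

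Kidney injury markers fell more often than they rose, 7 against 2 of 12. *HAVCR1*, which encodes the injury marker KIM-1, went from 355 ± 18.6 to 104 ± 14.2 CPM, *CLU* (clusterin) from 1142 ± 85.9 to 261 ± 7.78 CPM and *VCAM1* changed by -2.42 ± 0.08; *TIMP2* (0.66 ± 0.06) and *CD44* (0.56 ± 0.06) rose. *LCN2*, the gene of the injury marker NGAL, had 23.8 ± 2.52 CPM with vehicle and 26.6 ± 3.11 CPM with cyclosporine A and did not pass (edgeR adjusted p = 0.163). The list's camera adjusted p of 0.0229 became 0.251, again an adjusted p, with an estimated correlation. It also lost its call without vehicle replicate 2, 3 or 4 (adjusted p 0.0512, 0.0513 and 0.0512) or without cyclosporine A replicate 4 (0.0624). Of 25 listed proximal tubule markers 11 were tested, and these went both ways, 6 lower and 3 higher (camera adjusted p = 0.227). The membrane protease gene *MME* rose by 1.73 ± 0.07, whereas *PDZK1* (-2.01 ± 0.10) and the bicarbonate transporter gene *SLC4A4* (-1.80 ± 0.13) fell.

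Markers of other cell types were measured as a background. Of 18 listed markers of the distal and collecting tubule only 4 were tested, and all 4 fell, among them *SCNN1A*, a sodium channel subunit (-0.88 ± 0.06). The list had a camera adjusted p of 0.0277, and adjusted p = 0.251 with an estimated correlation. Its median level over both treatments was 3.04 CPM, near the floor, so this fall rests largely on low counts. *SLC12A3* (2.64 ± 0.165 CPM with vehicle) did not pass in DESeq2 (adjusted p = 0.0669). Of 5 endothelial, stromal and podocyte markers, 3 fell, *LUM* (-2.06 ± 0.07), *DCN* (-0.98 ± 0.08) and *SYNPO* (-0.81 ± 0.06), with a camera adjusted p of 0.0273 and adjusted p = 0.251 with an estimated correlation. Of 4 immune cell markers, *CD74* (-1.48 ± 0.06) and *CD14* (-2.64 ± 0.31) fell while *CSF1R* (1.60 ± 0.16) and *CD68* (0.39 ± 0.06) rose (camera adjusted p = 0.821).

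Interferon-stimulated genes fell in 9 of 18 cases, with 1 higher and 8 not passed. *IFITM1*, a membrane protein that restricts virus entry and whose reads may be shared with paralogs, changed by -2.81 ± 0.18 and *IFI6* by -1.39 ± 0.13, while *IRF1* rose by 0.68 ± 0.09. The camera adjusted p was 0.0277, and adjusted p = 0.345 with an estimated correlation. This call was also lost without vehicle replicate 3 (adjusted p 0.0580) and without cyclosporine A replicate 2 or 3 (0.0575 and 0.0556). Of 17 NF-kB and cytokine genes, 8 fell and 6 rose. *BIRC3*, an inhibitor of apoptosis, went from 521 ± 30.3 to 72.2 ± 3.42 CPM and *IL6* changed by -0.99 ± 0.10, whereas *TNFAIP3* rose by 0.83 ± 0.10. The median of this list was 0.05 and its mean -0.32, camera gave the direction as down, and the adjusted p was 0.666.

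**Figure D2:**
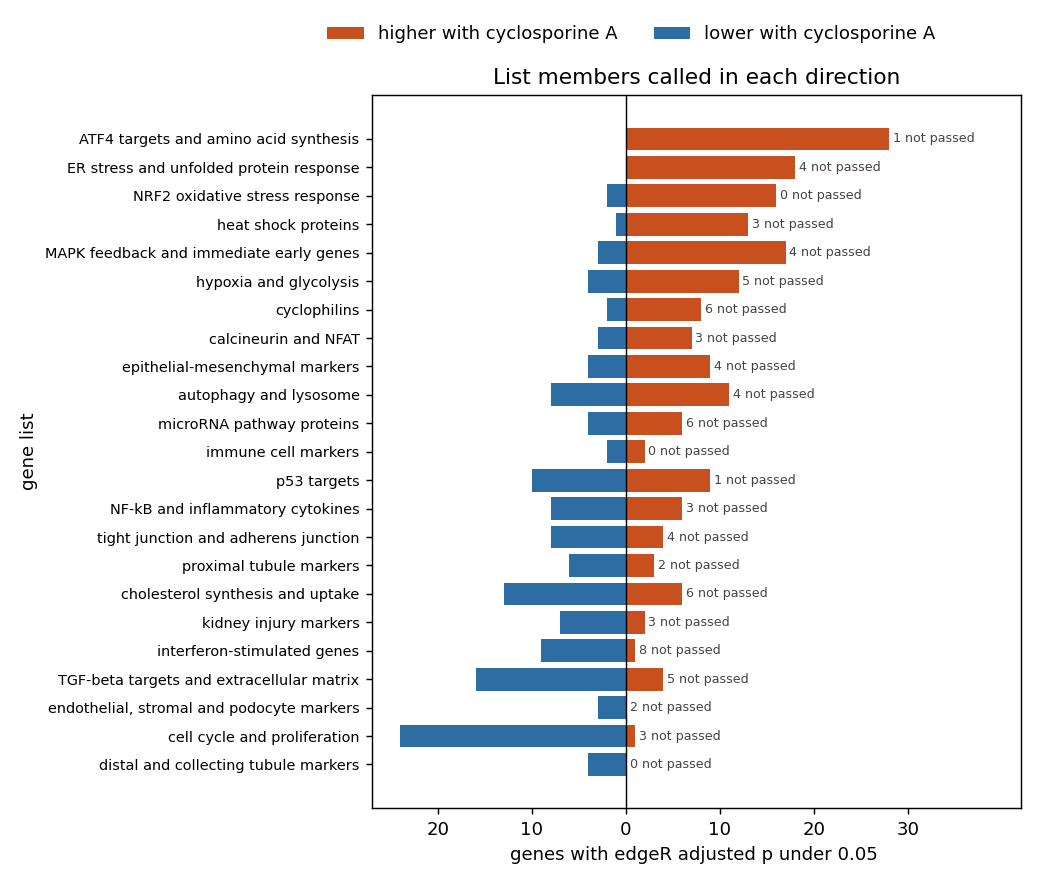
Number of genes of each fixed list with an edgeR adjusted p under 0.05 (horizontal axis, genes), higher with cyclosporine A to the right of 0 and lower to the left; the text at each bar gives the members that did not pass. The ATF4 list has 28 members to the right and none to the left, and the cell cycle list has 24 to the left and 1 to the right.

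The lists closest to the drug's direct targets had no camera call. In the calcineurin and NFAT list, 7 of 13 genes rose and 3 fell (camera adjusted p = 0.203). *RCAN1*, an NFAT-responsive regulator of calcineurin, had 5.97 ± 1.28 CPM with vehicle and 8.71 ± 0.964 CPM with cyclosporine A (0.58 ± 0.18, edgeR adjusted p = 0.00449). The calcineurin subunit genes *PPP3CA* (0.55 ± 0.08) and *PPP3R1* (0.64 ± 0.08) rose, and *NFATC4* (-1.30 ± 0.16) and the calcineurin anchoring protein gene *AKAP5* (-2.04 ± 0.29) fell. Of 16 cyclophilin genes, 8 rose and 2 fell (camera adjusted p = 0.201), led by the mitochondrial cyclophilin *PPIF* (1.34 ± 0.07). *PPIA*, the main cytosolic binding protein of the drug, had 45.2 ± 3.39 and 43.4 ± 0.873 CPM (-0.05 ± 0.08, edgeR adjusted p = 0.609); its reads can be split with processed pseudogenes, so its level is uncertain. *PPIB* differed by 0.13 ± 0.06 (edgeR adjusted p = 0.0551), and passed in DESeq2 (adjusted p = 0.0411), in limma voom (0.0499), without a filter on low counts (0.0459), with a replicate block (0.0493), and without vehicle replicate 3 (0.0255) or cyclosporine A replicate 4 (0.00947). Among 16 genes of the microRNA pathway, 6 rose and 4 fell (camera adjusted p = 0.203). *EIF2C2*, the gene of AGO2, went from 18.2 ± 0.570 to 44.2 ± 1.14 CPM and the miRNA-processing enzyme gene *DICER1* changed by 0.89 ± 0.06, whereas *DGCR8*, which acts upstream of it, changed by -0.96 ± 0.07.

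Cholesterol genes and autophagy genes each moved both ways. Of 25 genes of cholesterol synthesis and uptake, 13 fell and 6 rose (camera adjusted p = 0.298). *TMEM97*, a sterol-responsive membrane protein gene, fell (-0.73 ± 0.07), and *INSIG1* (0.67 ± 0.06), which restrains the pathway, rose. In the autophagy and lysosome list 11 of 23 genes rose and 8 fell (camera adjusted p = 0.392). The autophagy receptor gene *SQSTM1* went from 331 ± 5.86 to 1138 ± 25.7 CPM and *MAP1LC3B* changed by 1.63 ± 0.08, whereas the lysosomal protease gene *CTSB* changed by -0.61 ± 0.06. None of the 13 mitochondrially encoded mRNAs of the last list was among the features of the count table, so that list was not analysed here.

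The second comparison asked which miRNAs differ after 48 h of cyclosporine A, and the changes were fewer and smaller. Both arms of the miR-148a hairpin rose, hsa-miR-148a-5p by 1.02 ± 0.20 and hsa-miR-148a-3p by 0.68 ± 0.15 (n = 4 libraries per group). hsa-miR-222-5p had the largest rise of the named miRNAs, 1.14 ± 0.19. hsa-miR-155-5p, an miRNA of immune activation, rose from 6577 ± 571 to 9233 ± 534 CPM, and hsa-miR-29a-3p, which targets collagen mRNAs, from 4721 ± 395 to 6441 ± 376 CPM. hsa-miR-7-5p, an abundant miRNA, fell from 5236 ± 385 to 2581 ± 312 CPM, and hsa-miR-4485-3p (-1.43 ± 0.19), hsa-miR-7974 (-1.35 ± 0.15), hsa-miR-5091 (-1.17 ± 0.29) and hsa-miR-3687 (-0.98 ± 0.15) also fell. The sequence of hsa-miR-4485-3p also lay in an AGO2 cluster on the mitochondrial chromosome (hg19, chromosome M, 2523 to 2760, plus strand, annotated as non-coding), so its counts may include other RNA.

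hsa-miR-21-5p, the most abundant miRNA and one linked to kidney fibrosis, had 595720 ± 55875 CPM with vehicle and 594570 ± 123640 CPM with cyclosporine A, a log2 fold change of -0.0028 ± 0.13 (edgeR adjusted p = 0.991). Its libraries went both ways: cyclosporine A replicates 1 and 2 (475790 and 502600 CPM) lay below every vehicle library and replicates 3 and 4 (723310 and 676550 CPM) above every one. Before scaling, the shares of replicates 1 and 2 (55.7% and 57.7% of counts) lay inside the vehicle range of 54.7% to 60.7%, so the low side rests on the TMM factors. These factors parted in the same way, 1.17 and 1.15 against 0.865 and 0.908, and the rises of hsa-miR-148a-3p, hsa-miR-148a-5p and hsa-miR-222-5p were larger in replicates 3 and 4. Its other arm, hsa-miR-21-3p, differed by 0.32 ± 0.17 (adjusted p = 0.248). The next most abundant, hsa-miR-30a-5p (-0.06 ± 0.11), hsa-let-7i-5p (-0.31 ± 0.11), hsa-miR-26a-5p (0.01 ± 0.10) and hsa-let-7f-5p (0.07 ± 0.11), did not pass either, with edgeR adjusted p from 0.0901 to 0.986; hsa-let-7i-5p passed with RLE size factors (0.0467), with a replicate block (0.00833) and without cyclosporine A replicate 4 (0.0445).

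The edgeR test called 53 of 470 miRNAs, 23 higher and 30 lower. Without vehicle replicate 3 the counts were 14 and 15, and with a replicate block they were 43 and 49; the cause of the rise with the block was not tested. The authors' deposited table had 58 miRNAs with an adjusted p under 0.05, of which 50 were also called here, all with the same sign. Among the named miRNAs, hsa-miR-193a-3p (0.75 ± 0.18), hsa-miR-22-5p (0.58 ± 0.13) and hsa-miR-139-5p (0.53 ± 0.13) rose, and hsa-miR-577 (-0.79 ± 0.18), hsa-miR-335-3p (-0.76 ± 0.16), hsa-miR-449c-5p (-0.75 ± 0.14) and hsa-miR-4521 (-0.72 ± 0.16) fell. Calls that were lost when 1 library was left out included, besides those given with their lists below, those of hsa-miR-19a-3p (0.50 ± 0.13; adjusted p 0.0579 without vehicle replicate 3), hsa-miR-27b-5p (-0.63 ± 0.16; 0.0772 without vehicle replicate 3) and hsa-miR-92a-1-5p (0.67 ± 0.18; 0.0593 without cyclosporine A replicate 3).

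Lists of miRNAs fixed before the data were examined showed 1 camera call among 12. In the miR-221 and miR-222 list 1 of 4 members rose, 3 adjusted over the list alone, with a camera adjusted p of 0.0481 and adjusted p = 0.314 with an estimated correlation. This call was also lost without vehicle replicate 1 or 4 (adjusted p 0.0938 and 0.124) and without cyclosporine A replicate 1, 3 or 4 (0.0583, 0.0636 and 0.0571). Of 14 inflammation miRNAs, hsa-miR-155-5p, hsa-miR-212-5p (0.65 ± 0.17) and hsa-miR-132-3p (0.51 ± 0.15) rose; adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.162). The call of hsa-miR-132-3p was lost without vehicle replicate 1, 3 or 4 or cyclosporine A replicate 1 or 2 (adjusted p 0.0659, 0.0579, 0.0839, 0.0639 and 0.0791). Of 16 miRNAs linked to kidney fibrosis, hsa-miR-29a-3p and hsa-miR-29b-3p (0.46 ± 0.13) rose, as they did adjusted over the list alone (camera adjusted p = 0.685); hsa-miR-29b-3p was not called without vehicle replicate 1 or 3 (0.0659 and 0.115) or cyclosporine A replicate 3 or 4 (0.0598 and 0.0532). Of 7 muscle and endothelial miRNAs, hsa-miR-133a-5p (1.08 ± 0.28) and hsa-miR-133a-3p (0.52 ± 0.14) rose, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.135). hsa-miR-133a-3p lost its call without vehicle replicate 1 or 3 or cyclosporine A replicate 2 (adjusted p 0.0530, 0.0595 and 0.0556), and hsa-miR-133a-5p, at 1.30 ± 0.402 CPM with vehicle, without vehicle replicate 1 or 3 (0.0530 and 0.0579) and in DESeq2 (0.0626).

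In the hypoxia and stress list, 2 of 19 miRNAs fell (2 adjusted over the list alone), hsa-miR-27b-5p and hsa-miR-23b-5p (-0.78 ± 0.23), with a camera adjusted p of 0.805; hsa-miR-23b-5p, at 3.37 ± 0.498 CPM with vehicle, lost its call in DESeq2 (adjusted p = 0.145), with no filter on low counts (0.131) and without any 1 of 7 libraries (0.0532 to 0.123). hsa-miR-210-3p, the hypoxia-induced miRNA, differed by 0.22 ± 0.11 (edgeR adjusted p = 0.214). Of 23 miRNAs of the miR-17 to 92 paralog clusters, hsa-miR-19a-3p and hsa-miR-92a-1-5p rose, also adjusted over the list alone (camera adjusted p = 0.588); the median of this list was -0.01 and its mean 0.06, and camera gave the direction as up. In 6 lists no member passed in the edgeR fit with group as the only term, the default filter, TMM and all 8 libraries, over all miRNAs or adjusted over the list alone. Of 17 let-7 and miR-98 miRNAs, 4 had an unadjusted p under 0.05 and hsa-miR-98-5p (0.37 on the log2 scale) passed in DESeq2 (adjusted p = 0.0496), with a replicate block (0.0174), and without vehicle replicate 4 (0.0346) or cyclosporine A replicate 2 (0.0155); the camera adjusted p was 0.685. Of 17 kidney-enriched miRNAs, 4 had an unadjusted p under 0.05 and hsa-miR-30d-5p (-0.32 in DESeq2) passed in DESeq2 (adjusted p = 0.0329), in limma voom (0.0455), with RLE size factors (0.0269), with the stricter filter (0.0401), with a replicate block (0.00964) and without cyclosporine A replicate 3 (0.0451); the camera adjusted p was 0.135. Counts at an unadjusted p under 0.05 were 0 of 7 in the miR-200 family, 0 of 2 for miR-34 and miR-449, 1 of 2 for blood cell miRNAs and 1 of 8 in the 14q32 cluster, none of which DESeq2 or limma voom called (camera adjusted p 0.805, 0.510, 0.368 and 0.667); hsa-miR-381-3p of the 14q32 cluster passed without cyclosporine A replicate 1 (adjusted p = 0.0431), and hsa-miR-34a-5p with a replicate block (0.0340).

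The third comparison asked where AGO2 bound with and without the drug. The vehicle list held 56985 clusters and the cyclosporine A list 36812, with a median width of 20 bases in both. Introns held 24149 of the vehicle clusters (42.4%) and 15698 of the cyclosporine A clusters (42.6%), and intergenic sequence 46.9% (95% Wilson interval 46.5 to 47.3) and 46.8% (46.2 to 47.3). The 3' UTR, where most miRNA sites are known, held 1.31% (1.22 to 1.41) and 1.44% (1.32 to 1.57). Of the cyclosporine A clusters, 17764 (48.3%, 47.7 to 48.8) overlapped a vehicle cluster on the same strand, and 31.1% (30.7 to 31.5) of the vehicle clusters overlapped a cyclosporine A cluster. Clusters placed at random on their chromosome and strand overlapped in 0.0992% of cases on average and 0.136% at most over 20 placements. Any source of reads that recurs at the same loci, rRNA included, would exceed this share. The contrast therefore does not show that the shared clusters are AGO2 binding. Each condition has 1 pooled list, so no test between conditions was made; intervals cover counting error only, and a longer list can hold more of a shorter one.

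Clusters annotated as human rRNA held 13.9% of the vehicle and 18.1% of the cyclosporine A score, the authors' own value, whose unit is not stated and which is used here only within a list. Together with clusters that share 20 bases with one, of which some lie in introns, they were 0.595% of the vehicle and 0.886% of the cyclosporine A clusters and held 42.4% and 55.5% of the score. The guide strand of miR-21 was captured at its own locus, with a score of 2370 in the vehicle list (hg19, chromosome 17, 57918635 to 57918660, plus strand, annotated as promoter-TSS of *MIR21*, sequence AGCTTATCAGACTGATGTTGACTGTT) and 3315 in the cyclosporine A list. A cluster at *MIR22* (hg19, chromosome 17, 1617209 to 1617229, minus strand, promoter-TSS, sequence AAGCTGCCAGTTGAAGAACTG) had a score of 2284 in the cyclosporine A list; both loci were chosen after the lists were seen.

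Clusters annotated to introns did not keep to 1 strand under a gene symbol. Genes here are the symbols of the lists, which need not be the gene that holds the intron. *MIR1268A*, for example, labels intron clusters on chromosome 9 and on chromosome 8 in the vehicle list. In genes with 2 or more intron clusters, the first 2 lay on the same strand in 51.9% of 4609 genes in the vehicle list (50.4 to 53.3) and in 50.4% of 3168 genes in the cyclosporine A list (48.6 to 52.1). The share was 60.7% (53.9 to 67.1) and 69.6% of 102 genes (60.1 to 77.7) for exon clusters, and 72.9% of 118 genes (64.2 to 80.1) and 75.0% of 56 genes (62.3 to 84.5) for clusters at promoters. For 3' UTR clusters it was 60.5% of 38 genes (44.7 to 74.4) and 66.7% of 39 genes (51.0 to 79.4). Stretches of 13 bases conserved in bacterial ribosomal RNA occurred in 158 of 56579 vehicle clusters searched and in 109 of 36414 cyclosporine A clusters, against at most 4 and 5 for shuffled, reversed or reverse complement controls. The set of stretches was revised after a first count, and in part after a cluster sequence was seen. The contrast with the controls is therefore not an independent test.

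**Figure D3:**
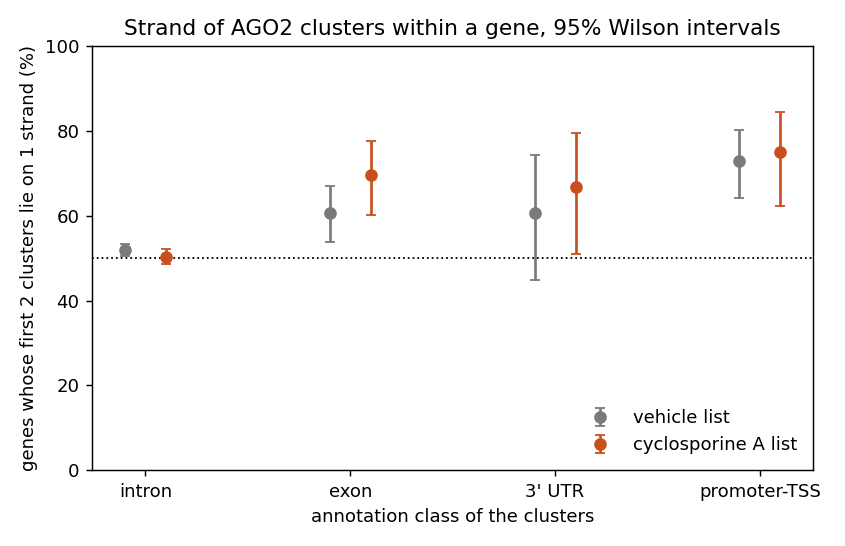
Share of gene symbols (vertical axis, percent) whose first 2 AGO2 clusters of an annotation class lie on the same strand. Bars are 95% Wilson intervals for the vehicle and cyclosporine A lists, and the dotted line marks 50%. Intron clusters lie at 51.9% and 50.4%, and promoter clusters at 72.9% and 75.0%.

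Genes with clusters annotated as 3' UTR, on either strand, numbered 708 in the vehicle list and 487 in the cyclosporine A list. *ADRB1*, a beta-adrenergic receptor gene, had the highest 3' UTR score in both, 11271 for the vehicle cluster (hg19, chromosome 10, 115805664 to 115805687, plus strand) and 14932 for the cyclosporine A cluster, which was 10.0% and 15.8% of all 3' UTR score. *ADRB1* mRNA was at 4.72 and 4.84 CPM, and both clusters held one of the conserved bacterial rRNA stretches; a stretch that matches them was added to the search after their sequence was seen. The next scores in the vehicle list were those of *GUCY1A2* (6275), *ZYG11A* (5845), *HLCS* (4545) and *FFAR4* (4165), and in the cyclosporine A list those of *FBLN1* (2817), *SLC25A36* (2561), *CMBL* (2536) and *FFAR4* (2089). The clusters of *GUCY1A2* and *HLCS* are listed on the plus strand and those of *FFAR4* and *FBLN1* on the minus strand, opposite to these genes, so they are not in the genes' own 3' UTR RNA. Among the named mRNA genes, *DUSP5* and *SOX4* had a 3' UTR cluster in the vehicle list, with scores of 45 and 18, and *HSPA5* and *SNAI2* in the cyclosporine A list, with 65 and 48. *SOX4*, a kidney injury list gene, changed by -1.75 ± 0.06 in mRNA.

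The last comparison asked whether the mRNA of genes with AGO2 clusters annotated to their 3' UTR shifted in 1 direction against other genes. Clusters on either strand were taken, so some members need not carry AGO2 on their mRNA, and a lack of shift says little about AGO2 targets. Over all tested genes, 4285 of 12855 rose and 4312 fell. Of 160 tested genes with clusters in both lists, 69 rose and 47 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.273). Of 213 with clusters only in the cyclosporine A list, 85 rose and 69 fell, or 89 and 70 adjusted over the list alone (camera adjusted p = 0.273). Of 369 with clusters only in the vehicle list, 148 rose and 126 fell, again with the same counts adjusted over the list alone (camera adjusted p = 0.506; median 0.04, mean -0.01, direction up). Camera called none of these 3 sets, with the preset or an estimated correlation, and none had an unadjusted p under 0.05 (0.176, 0.182 and 0.506).

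Sites for miRNA seeds were counted in the clusters themselves. The 7-base sites of 14 of 52 families in the vehicle list, and of 13 in the cyclosporine A list, occurred in more clusters than in any of 20 dinucleotide shuffles of the same sequences. Among them were sites of miR-21 (80 vehicle clusters against a shuffled mean of 46.4), the pair miR-221 and miR-222 (85 against 40.8) and miR-27 (296 against 180). Sites of other abundant families lay below their shuffled mean in the vehicle list, with let-7 at 19 against 24.0, miR-26 at 47 against 82.3 and the miR-200b family at 29 against 33.6. miR-30 passed (68 against 42.9) but did not with mononucleotide shuffles (highest 77). None of the 7 families fixed as controls because they are typical of other tissues passed in either list with these shuffles. Several of them are present in these cells, with hsa-miR-126-3p at 1011 CPM, hsa-miR-1-3p at 407 CPM and hsa-miR-142-3p at 118 CPM with vehicle, so they do not stand for absent miRNAs. Sites read in mirror image, which no miRNA of these families would bind, passed for 16 families in the vehicle list and 11 in the cyclosporine A list.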

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

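All 16 values in this part were picked by a single test set before the data were examined, and no test here was chosen after a result was seen. Within each group of 4 libraries, the gap between the most distant library and its nearest neighbour was divided by the whole range of the group (Dixon ratio). Of 340 groups tested, of the named genes and miRNAs reported here and of library totals, 16 exceeded the 95% critical value, which chance does in about 1 in 20 groups. The 16 are thus no more than chance alone would give.

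Among mRNA genes of vehicle libraries, replicate 4 was the lowest for *SLC34A2* (ratio 0.859; 65.7 CPM against 76.6 to 78.3), *LRG1* (0.951; 37.9 against 44.9 to 45.3), *IL6* (0.926; 38.4 against 48.7 to 49.5) and *CLU* (0.864; 1014 against 1173 to 1198). Replicate 1 was the highest for *TGFB2* (0.882). Replicate 2 was the lowest for *SLC12A3* (0.842) and *HK2* (0.875) and the highest for *LCN2* (0.900; 27.6 CPM against 22.3 to 22.8), and replicate 3 the highest for *HSPA1A* (0.888). Vehicle replicate 4 thus holds 4 of the 16, and vehicle numbers 1 and 2 hold 3 each over both RNA classes. These flags take each gene alone, so they cannot show a smaller shift that many genes share. Among the largest falls, vehicle replicate 4 was also lowest for *MMP7*, *FLRT3*, *STAT4*, *PLIN5* and *CLDN2* (67.7 CPM against 91.1 to 102). It was not the lowest for *DEFB1*, *SAA2* and *CDH16*. Cyclosporine A replicate 3 was the lowest of its group for several genes that rose, as given above. The 4 genes, *SLC34A2*, *LRG1*, *IL6* and *CLU*, also fell with cyclosporine A by 0.99 or more on the log2 scale. This was read after the flags were seen. In genes that fell, a low vehicle value lies toward the cyclosporine A values by construction. Among the largest rises, vehicle replicate 4 was the lowest vehicle library only in *HES1* (3.84 CPM), away from the cyclosporine A values. It was the highest, toward those values, in *PLIN2* (94.8 CPM against 76.5 to 83.4), *GADD45A* (44.7 against 34.7 to 41.2) and *UPP1* (36.6 against 31.5 to 34.3). Other genes that rose went both ways, with *AARS*, *TXNRD1* and *FTL* highest and *DDIT3*, *HSPA5* and *SLC3A2* lowest in it. Whether this library leans toward the cyclosporine A values was not tested. With cyclosporine A the mean of *CLU* was 261 CPM and that of *IL6* 23.4 CPM. Without vehicle replicate 4 the log2 fold change of *IL6* was -1.06 in place of -0.99.

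With cyclosporine A, replicate 1 was the highest for *SAA2* (0.934; 1.85 CPM against 0.690 to 0.767) and the lowest for *DGCR8* (0.872), replicate 3 was the lowest for *HSPA1B* (0.838; 88.1 CPM against 165 to 180) and replicate 4 the highest for *JUP* (0.948). Reads of *HSPA1B* may be shared with its near copy *HSPA1A*, so its separate level is uncertain. Among miRNAs, vehicle replicate 1 was the lowest for hsa-miR-148a-3p (0.944) and hsa-miR-4521 (0.918; 69.1 CPM against 114 to 118), and cyclosporine A replicate 3 the highest for hsa-miR-335-3p (0.869).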

How the results depend on the processing

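All alternatives here were fixed before the data were examined, except the seed count in 3' UTR clusters alone, which was chosen after the result was seen. Counts of mRNA genes ranged from 3651 to 4472 higher and from 3913 to 4947 lower over DESeq2, other normalizations, filters, limma voom and single libraries left out; upper quartile normalization gave 3651 and 4947, so the even balance of directions depends on the scaling. Calls shared with the edgeR fit had the same direction under every alternative. With the correlation estimated, camera called 0 of the 23 gene lists in place of 12, and 0 of the 12 miRNA lists in place of 1; with the stricter filter 11 gene lists were called, as the distal tubule list had too few genes left. None of the 117 named mRNA genes lost its call without a library, and *SLC12A3* lost it in DESeq2. miRNA calls ranged from 14 to 29 higher and from 15 to 29 lower without 1 library, lowest without vehicle replicate 3, and called miRNA lists from 0 to 1. For 53 named miRNAs, of the values without 1 library 390 kept their side of the threshold, 24 lost a call, 10 gained one and 0 changed sign past it.

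A block for the replicate number gave 43 higher and 49 lower miRNAs in place of 23 and 30, and 4243 higher and 4243 lower mRNA genes; the cause was not tested. With the block, hsa-miR-98-5p (adjusted p = 0.0174), hsa-let-7i-5p (0.00833), hsa-let-7b-5p (0.0281), hsa-miR-34a-5p (0.0340), hsa-miR-30d-5p (0.00964), hsa-miR-19b-3p (0.0293), hsa-miR-143-3p (0.00986), hsa-miR-221-5p (0.00977) and hsa-miR-222-3p (0.0267) passed, which they did not with group as the only term; the last 2 would raise the miR-221 and miR-222 list from 1 to at least 3 of 4 members. Deviations of libraries sharing a number correlated between -0.0841 and 0.033 for mRNA and between -0.0599 and 0.338 for miRNA. Libraries of different numbers correlated between -0.0822 and 0.144 for mRNA and between -0.283 and 0.179 for miRNA. For miRNA the highest value was thus of a shared number, and a shared effect of the number stays open there. The main fit kept group as its only term.

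The share of cyclosporine A clusters overlapping a vehicle cluster was 47.4% with a score of at least 20 and 42.04% with the same number of clusters per list. The vehicle shares were 33.9% and 41.96%. Overlapping clusters number nearly the same from either list (15475 and 15447 at equal lengths). The 2 shares therefore differ with list length by construction, and their match at equal lengths is no test. Mononucleotide shuffles gave 25 and 24 seed families in place of 14 and 13, and 3' UTR clusters alone 4 and 3. Control families were among these: miR-223 and miR-124 in both lists with mononucleotide shuffles, and the family of miR-1 in the 3' UTR clusters of the cyclosporine A list. No AGO2 target set was called under any alternative. The sets per seed family, and their alternatives, were not run, since no family reached 10 genes.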

Other observations

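Some tests in this part were chosen after the result they measure was seen: the 3 tests of intron clusters and the counts over other splits of the libraries. The gene sets and pairings were chosen after the named genes had been seen, but before their own values were. Members of the miR-23a and miR-23b clusters, close paralogs at different loci, are given as values; a difference between the clusters was not tested. hsa-miR-23a-3p (0.46 ± 0.14), hsa-miR-27a-3p (0.40 ± 0.11) and hsa-miR-27a-5p (0.61 ± 0.19) rose with cyclosporine A, whereas hsa-miR-27b-5p (-0.63 ± 0.16) and hsa-miR-23b-5p (-0.78 ± 0.23) fell, with edgeR adjusted p from 0.0161 to 0.0477; these members were picked after their values were seen. Of the miR-23a cluster, hsa-miR-24-2-5p did not pass (0.20 ± 0.13, edgeR adjusted p = 0.337), and hsa-miR-23a-5p had a log2 fold change of 1.19. The abundant arms of the miR-23b cluster did not pass, with hsa-miR-23b-3p at 0.07 ± 0.13, hsa-miR-27b-3p at -0.11 ± 0.11 and hsa-miR-24-3p, which both clusters make, at -0.0086 ± 0.10. The arms that fell are minor ones, at 16.9 CPM for hsa-miR-27b-5p and 3.37 CPM for hsa-miR-23b-5p with vehicle, and both lose their call when single libraries are left out. Without vehicle replicate 3, for example, the adjusted p was 0.0772 for hsa-miR-27b-5p and 0.123 for hsa-miR-23b-5p. hsa-miR-10a-5p (-0.47 ± 0.11) and hsa-miR-10b-5p (-0.39 ± 0.11) both fell, as did hsa-miR-425-5p (-0.56 ± 0.15), hsa-miR-425-3p (-0.53 ± 0.12) and hsa-miR-191-5p (-0.39 ± 0.12), which come from 1 cluster.

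The sample made with an antibody to all Argonaute proteins, whose treatment the labels do not give, held 19306 clusters. Of these, 44.2% overlapped a vehicle AGO2 cluster and 37.6% a cyclosporine A one. *ADRB1* again had the highest 3' UTR score (5054), followed by *ECT2* (2289) and *DDAH1* (2130).

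Changes of both arms of a hairpin went together. Over 109 hairpins, the log2 fold changes of the 5p and 3p arms had a Pearson r of 0.533 (permutation p = 1e-05, the smallest that these permutations can give; 2e-05 adjusted), which was 0.389 without the 2 farthest pairs, and 67 pairs had the same sign. This is consistent with a change in the shared precursor for part of the miRNAs. The mRNA of the host gene gave no such relation: over 34 pairs r was 0.175 (permutation p = 0.323) and 18 pairs had the same sign. *DALRD3* (-0.41) and its miR-191 and miR-425 (mean -0.50) fell together, while *MIR210HG* changed by -1.28 and miR-210 by 0.18, so the part played by host gene transcription stays open.

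Acute phase and complement genes other than *SAA2*, *LRG1* and *DEFB1* fell in 7 of 8 cases, with *SAA1* at -3.49, *SERPINA1* at -1.81, *CFB* at -1.69 and *C3* at -0.69; *CP* (0.21) did not pass. The camera adjusted p was 0.000667, and adjusted p = 0.208 with an estimated correlation. Only 8 of the 16 listed genes were tested. *SAA1* is a near copy of *SAA2* and may share its reads, so its fall is not separate from that of *SAA2*. Within these limits, the fall of *SAA2* and *LRG1* may belong to a wider fall of this group, as a hypothesis. Of 15 cytosolic tRNA synthetase genes outside the ATF4 list, 12 rose, among them *YARS* (1.22) and *IARS* (1.03), and *QARS* (-0.37) fell. Their camera adjusted p was 0.000336, and adjusted p = 0.346 with an estimated correlation. Of 17 mitochondrial synthetases 3 rose and 9 fell (camera adjusted p = 0.243), so a rise of all synthetases is not shown.

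The largest single rises were not matched by a called rise of their wider groups. Of 28 PPAR target genes other than those named in the report, 16 rose and 7 fell, or 16 and 8 adjusted over the list alone (camera adjusted p = 0.299). Of 20 other vacuolar ATPase subunits, 10 rose and 7 fell (0.243), and of 11 other Notch receptors, ligands and targets 5 rose and 4 fell (0.975; median -0.26, mean 0.0021, direction up). Whether *ANGPTL4*, *ATP6V0D2* and *HES1* rose through these pathways stays open.

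Intron clusters of AGO2 were weighed against 1 biological and 2 technical explanations. AGO2 on RNA of the host gene would put the first 2 clusters of a host on 1 strand, and they were so under 51.9% of gene symbols. A symbol need not be the host gene and can cover more than 1 locus, which lowers the share. The interval of the share was 50.4 to 53.3, and the share in the cyclosporine A list was 50.4%, both near an even split of strands. For the symbols counted, these shares argue against host transcripts as the main origin, unless most symbols do not stand for the host. How often that holds was not measured. A strand column without information would give the same share everywhere, but promoter clusters stood at 72.9%. Conserved stretches of bacterial rRNA lay in 158 vehicle clusters, 73 of them in introns and 78 intergenic, so reads from bacteria may be among them, but these are a small part of all clusters and the origin of the rest stays open. The set of stretches was revised after a first count, so this count is not an independent test.

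Seed site counts depend on base composition. Mirror-image sites exceeded all shuffles for 16 families in the vehicle list, against 14 for the true sites, and for 11 against 13 in the cyclosporine A list, so composition beyond dinucleotides could produce counts of this size and the seed counts alone do not show miRNA binding.

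The fall of hsa-miR-4485-3p and hsa-miR-3687 might come from rRNA fragments counted as miRNA. The other miRNAs at rRNA-like clusters had a median of 0.0524, with hsa-miR-6087 at 0.09 ± 0.21, hsa-miR-663b at 0.05 ± 0.26 and hsa-miR-7641 at -0.48 ± 0.26. These other miRNAs are too few and too uncertain to tell the explanations apart. The sequence of hsa-miR-4485-3p itself lay in a vehicle cluster on the mitochondrial chromosome with a score of 763. Vehicle clusters elsewhere that hold it, the one at *MIR4485* included, scored 23 to 33. Whether its miRNA counts come from the mitochondrial RNA was not tested.

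Other splits of the 8 libraries into 4 and 4 did not give as many calls. For mRNA, 1 of 35 splits, the real one, gave 8597 genes, and the highest of the others gave 0 (1292 at an unadjusted p under 0.05 in edgeR). For miRNA, 1 of 35 splits, again the real one, gave 53, and the highest other gave 2. Every other split mixes both treatments within a group, which widens the spread where they differ and lowers the counts of those splits. The real split is 1 of 35, the smallest share that 35 splits can give. Chance in how libraries fell into groups is thus unlikely as the origin of these counts, but it is not excluded.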
